A study of Mus musculus with 5 samples.

How the data were processed

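Lungs of 5 C3H mice that had been sensitised to and challenged with ovalbumin, the egg-white protein used as an allergen in mouse models of allergic airway inflammation, were compared with a pool of control C3H lungs. C3H is an inbred mouse strain. RNA was amplified before labelling, per the labels, and each ova mouse was hybridised against the control pool on its own 2-colour array, so the series holds 1 group of 5 arrays. The labels number the ova mice 1 to 5 as separate animals. The number of control mice in the pool is not given in the sources used here, nor are the dyes, the days of sensitisation and challenge, the scanner, the background correction or the within-array normalization.

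The deposited table gives 1 value per probe and array, in the unit of a log2 ratio as read here. The authors' processed values, whose upstream steps are not given in the sources used here, are signed, have array medians of 0.008, 0.004, -0.015, -0.006 and 0.003 for mice 1 to 5, and are blank where no value was given. Neither the log base nor the numerator is stated in the deposited table. A base of 10 can be ruled out, since the largest size, 5.168, would exceed the log10 range of a 16-bit scanner, 4.82. Base 2 was taken; under the natural logarithm every value would be the same but every fold larger, so that the largest size is 36.0-fold under base 2 and 175.6-fold under base e. Tests against 0 do not depend on the base, apart from the one against a minimum size. Brightness, saturation and background of the spots were not available to any step, so faint spots could be recognised only where they were left blank.

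The labels do not settle the direction of the ratio. Of 7 genes known to rise in allergic airways, 6 lay past the threshold below 0 and 0 above it. This argues against a ratio of ova over control, as set out below. The titles name the ova mouse before the pool, which would make values above 0 an excess in the ova lungs, but no dye or numerator is given. Results are therefore given as lying on the negative side (below 0) or the positive side (above 0) of the deposited ratio. All pairs of arrays correlated above 0 across probes, so the 5 arrays ran the same way; a dye effect that is constant across arrays cannot be separated from the comparison.

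The table has 17280 probes, of which 2247 had no value on any array. Gene names came from the platform annotation in GEO's records, which gave 1 gene symbol for 14722 probes, several for 1 and none for 2557. Of the probes with 1 symbol, 14445 had a gene identifier in the reference gene table of assembly GRCm38.p6, which changed 0 symbols. The files name no genome build, so no coordinates are given. Each array was centred on its median. Probes with a value on at least 4 of the 5 arrays were tested, 11714 in all. For genes, the log ratios of all probes naming only that gene were averaged per array, giving 9727 genes with values on at least 4 arrays.

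Each probe and each gene was tested against a log ratio of 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The pool counts as 1 control sample: this test measures the spread among the ova mice and leaves out the spread among control mice. With 5 arrays an exact sign test cannot go below a two-sided p of 0.0625, so single genes rest on the model. Before the data were examined, 35 gene lists were fixed for cell types and pathways of the lung and of allergic inflammation; 707 of their genes were measured. Lists were tested on the moderated statistics with limma's cameraPR, which asks whether a list's genes differ from the other genes, with a preset inter-gene correlation of 0.01. The same test was run with a correlation estimated per list from these 5 arrays (an imprecise estimate) and on ranks, and limma's fry (with statmod 1.5.0), which tests whether a list's genes move on balance to 1 side without comparing them with other genes, was run on genes with values on all arrays. Members are counted after adjustment over all genes and, in brackets where it differs, adjusted over the list alone.

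The genes named are, by a rule fixed before the data were examined, the 12 with the largest mean ratio on each side among genes past the threshold and on 1 side in every array that measured them, the 3 members of smallest p in each list past its test, and the response genes of allergic airway inflammation Clca1, Retnla, Arg1, Ccl11, Muc5ac, Rnase2a (formerly Ear11), Il13ra2, Sftpc and Scgb1a1. Chil3 and Chil4 were also on that list and have no named probe here. Other genes named as members of a list were chosen after their values were seen.

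On simulated data with the real spread and blanks of the 11714 probes, 97.0% of probes shifted by 1 and 44.6% of those shifted by 0.3 were recovered, and 4.58% of calls were false. In each run 200 probes were shifted, so the share recovered need not hold where more probes differ. A list shifted by 0.3 was found in 20 of 20 simulated runs, and 4 of 700 unshifted lists passed. Genes were simulated as independent, whereas the correlation estimated from the arrays was, for example, 0.537 in the alveolar type 1 list. These runs therefore do not check the preset correlation or the p-values that rest on it. Alternatives were other centring and scaling, other limits on blanks, a robust variance model, array weights, a minimum size, 1 probe per gene, other list tests and leaving out each mouse. Figures and position tests used Python 3.11.15. After the data had been seen, 2 more alternatives were added: leaving out probes at certain ID distances from a stronger probe, and subtracting the median of windows of 480 consecutive probe IDs. The number of arrays limits the precision of every value.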

Results

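Gene expression in the lungs of 5 ovalbumin-sensitised and challenged C3H mice (ova mice) was measured against a pool of control C3H lungs on 2-colour arrays, 1 array per ova mouse. Between 11778 and 13320 of the 17280 probes had a value on an array, and 9464 had a value on all 5. The question set by the design was which genes differ between the inflamed and the control lung. The labels do not state which sample is the numerator of the deposited log ratio, so a gene is described by its side of that ratio. Values are on the deposited log scale, taken as log2, after centring each array on its median, and are means over 5 mice (with SD where given) unless n is stated.

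Pearson's r across probes was between 0.64 and 0.83 for the 10 pairs of arrays, with a median of 0.736; probes are not independent replicates. All arrays share the control pool, whose own deviations push the 5 ratios of a probe the same way and raise r without any effect of ovalbumin, by an amount that these files cannot give. Pairs of arrays shared between 9 and 36 identical values, so no array was a copy of another. Of the 9464 probes with 5 values, 40.6% lay on 1 side in all mice, to which the shared pool also contributes. The median SD between mice was 0.128 per probe. The arrays differed in the size of their ratios: the SD across probes was 0.20 in mouse 1 and between 0.32 and 0.38 in mice 2 to 5. Over the 755 genes past the threshold whose mean ratio in mice 2 to 5 was beyond 0.5 in size, the ratio in mouse 1 was 0.453 of that mean (median). For mice 2 to 5, each set in the same way against its other 4 mice, the median was 1.12, 0.976, 0.937 and 1.33.

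In total 3095 of 11714 probes (2656 of 9727 genes) differed from 0 at an adjusted p under 0.05 in limma's moderated test. Of these probes, 1726 lay on the negative side and 1369 on the positive side. The large ratios were mainly on the negative side: 130 probes past the threshold lay below -1 and 23 above 1, and 21 lay below -2 and 0 above 2. Counted as genes, 123 lay below -1 and 12 above 1. Several of the 23 positive probes name the same gene, Hspa1a, which has 17 probes. Without mouse 1 the numbers of probes beyond a size of 1 were 164 and 38. The count of probes past the threshold varied with the mouse left out: it was 1869 without mouse 3 and 1862 without mouse 5, and the positive side held 885 probes without mouse 2. In these fits probes needed values on at least 3 arrays, so 12477 probes were tested without mouse 3 and 12111 without mouse 5. Fewer arrays also played in, as the count fell whichever mouse was left out, to 2940 at most. Tested against a minimum size of 0.5 with limma's treat, 72 probes passed, 67 of them negative.

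The 12 genes with the largest mean ratios on the negative side were led by Retnla, which encodes the secreted protein RELM-alpha of alternatively activated macrophages and airway epithelium. Retnla had a mean ratio of -4.79 ± 0.30 (SD, n = 5; 27.7-fold if the log base is 2, which is not stated; limma adjusted p = 7.63e-07). Clca1, a marker of mucus-producing goblet cells, followed at -4.33 ± 0.40 (adjusted p = 4.01e-06). Rnase2a, an eosinophil-associated ribonuclease, stood at -4.23 ± 0.60, and Saa3, an acute-phase serum amyloid A, at -3.88 ± 0.80. Arg1, the arginine-degrading enzyme arginase 1, had -3.48 ± 1.23 and was the most variable of these genes, between -2.27 in mouse 4 and -4.89 in mouse 2. The chemokines Cxcl9 (-3.47 ± 0.88) and Ccl8 (-2.89 ± 1.10), the trefoil peptide gene Tff2 (-3.32 ± 0.51, n = 4), the anion exchanger gene Slc26a4 (-3.31 ± 0.68) and the mucin gene Muc5ac (-3.00 ± 0.55) completed the group together with Sar1a (-3.22 ± 0.51) and Kctd9 (-2.71 ± 0.18). The probes of Sar1a and Kctd9 lie 18 and 24 IDs from that of Clca1, distances at which ratios of probes not naming the same gene correlated. All 12 lay below 0 in every mouse that measured them, with adjusted p-values of 0.00165 or less.

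**Figure D1:**
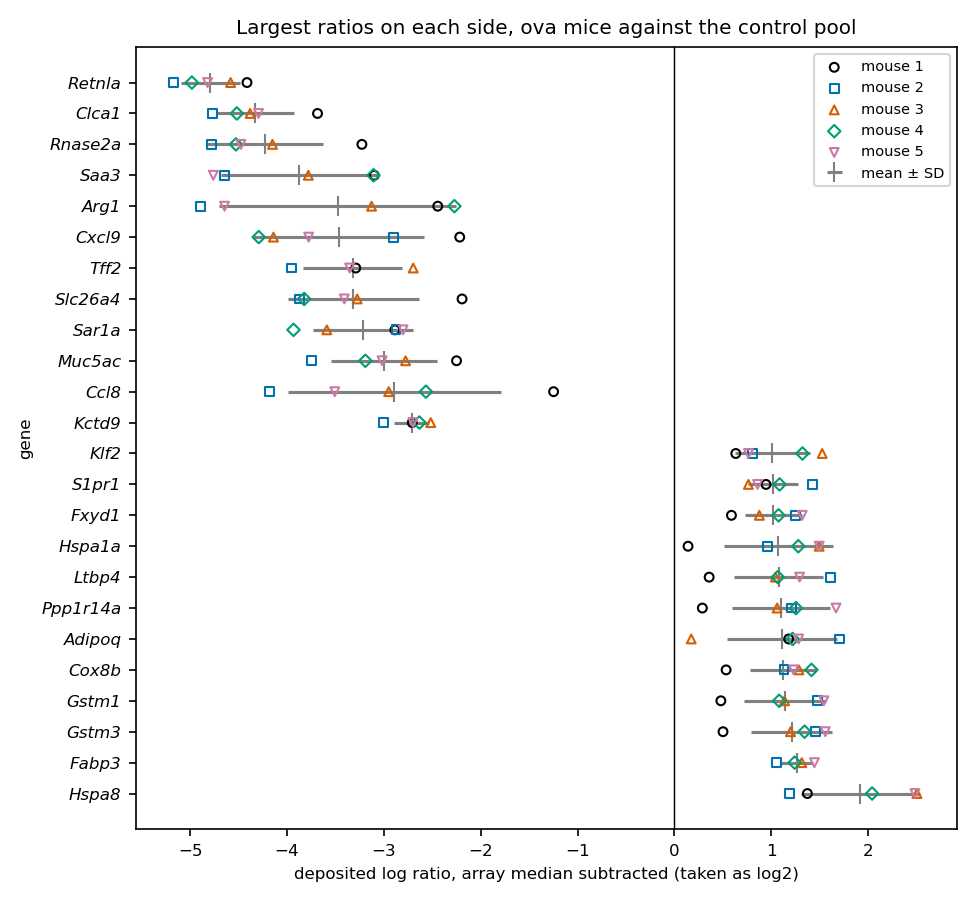
Log ratios (x axis, deposited scale taken as log2, array median subtracted) of the 12 genes with the largest mean ratio on each side; symbols are the 5 ova mice and grey bars the mean ± SD. Retnla lies near -4.79 and Hspa8, the largest on the positive side, near 1.92, and mouse 1 often lies closest to 0.

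The positive side held smaller ratios. Hspa8, a constitutive heat shock cognate chaperone, had a mean of 1.92 ± 0.62 (n = 5, limma adjusted p = 0.000979), and Hspa1a, a stress-inducible chaperone with 17 probes, 1.07 ± 0.57. Hspa1a had a ratio of 0.14 in mouse 1 and 1.49 in mice 3 and 5. The heart and fat fatty acid binding protein gene Fabp3 (1.26 ± 0.16, n = 4), the muscle and brown fat cytochrome oxidase gene Cox8b (1.12 ± 0.34) and Adipoq, the fat hormone adiponectin (1.11 ± 0.56), were among the 12. Adipoq was 0.17 in mouse 3 and between 1.18 and 1.70 in the others. The glutathione S-transferase genes Gstm3 (1.21 ± 0.42) and Gstm1 (1.14 ± 0.42) stood beside the smooth muscle phosphatase inhibitor gene Ppp1r14a (1.10 ± 0.50), the matrix gene Ltbp4 (1.07 ± 0.46) and the ion transport regulator gene Fxyd1 (1.02 ± 0.30). The sphingosine-1-phosphate receptor gene S1pr1 (1.01 ± 0.26) and the endothelial flow-responsive transcription factor gene Klf2 (1.01 ± 0.39) completed the group. Gstm1, 2 and 3 are related genes of 1 family whose probes may share signal, which was not tested.

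The response genes of allergic airway inflammation fixed in advance fell on both sides. Clca1, Retnla, Arg1, Muc5ac and Rnase2a are given above. Ccl11, the eosinophil chemoattractant eotaxin-1, was also on the negative side at -0.94 ± 0.40 (adjusted p = 0.00264, n = 5). Il13ra2, the decoy receptor for interleukin-13, gave 0.01 ± 0.11 (n = 4, limma adjusted p = 0.918). The surfactant protein gene Sftpc (0.67 ± 0.39) and the club cell secretory protein gene Scgb1a1 (0.70 ± 0.36, n = 4) were on the positive side, with limma adjusted p-values of 0.00861 and 0.00909. Thus 6 of the 7 genes known to rise in allergic airways lay past the threshold on the negative side and 0 on the positive side.

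Gene lists were then compared with all other genes. In limma's cameraPR with the preset correlation, 17 of 35 lists passed an adjusted p of 0.05, 13 toward the negative and 4 toward the positive side. With a correlation estimated per list, 4 remained: cell cycle, alternatively activated macrophages, mucus and chemokines. For each list the median, the mean and the test had the same sign. Some lists share genes, among them C1qa and C1qb under macrophages and complement, Mrc1 (-1.23) under both macrophage lists, and Cav1 under endothelium and alveolar type 1 cells. Alox15 counts under eosinophils and alternatively activated macrophages, and Cxcl1 under neutrophils and chemokines. The probe of Mrc1 lies 18 IDs from that of Mmp12 (-2.30).

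Genes of chitinase-like proteins and alternatively activated macrophages had the largest list median, -1.03. Of 16 measured members, 12 passed on the negative side, 0 on the positive side and 4 did not pass. Chia1, an acidic chitinase, had -2.19 ± 0.37, the lectin receptor gene Clec10a -1.72 ± 0.52 and Chil1, a chitinase-like protein gene, -1.13. The list gave an adjusted p of 7.86e-18, and adjusted p = 0.011 with an estimated correlation.

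Of 18 measured mucus and goblet cell genes, 12 passed on the negative side and 2 on the positive side, with a list median of -0.57. Besides Clca1, Muc5ac and Tff2, these included the mucin genes Muc5b (-1.32, n = 4) and Muc4 (-1.06), the protein disulfide isomerase gene Agr2 (-1.21), the goblet cell transcription factor gene Spdef (-0.47) and Itln1, an intelectin (-0.77). Bpifa1, a secreted airway defence protein gene, and Creb3l4 were on the positive side at 0.55 and 0.26. The adjusted p was 5.09e-14, and adjusted p = 0.00286 with an estimated correlation.

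Of 37 cell cycle genes, 30 passed on the negative side and 0 on the positive side (31 and 1 adjusted over the list alone), with a median of -0.57. The mitotic kinase gene Cdk1 had -2.14 ± 0.51, the mitotic kinesin gene Kif20a -1.59 ± 0.28 and the histone variant gene H2az1 -0.80 ± 0.14. The probe of H2az1 lies 24 IDs from that of Ccl12 (-1.07), and that of Fen1 18 IDs from another strong probe. Members of the replication machinery such as Mcm7 (-1.06), Fen1 (-1.02) and Rrm2 (-0.90, n = 4) passed on the same side, while Mki67 (-0.20) and Top2a (-0.39) did not pass. The list had an adjusted p of 1.39e-21, and adjusted p = 0.0462 with an estimated correlation.

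Of 21 chemokine genes, 14 passed on the negative side (15 adjusted over the list alone) and 2 on the positive side. Cxcl9, Ccl9 (-2.69 ± 0.88) and Ccl1 (-1.30 ± 0.43) had the smallest p, and Cxcl11 had -1.13. Cxcl12 (0.50) and Cxcl14 (0.39), homeostatic chemokine genes, were on the positive side. Ccl24, eotaxin-2, gave 0.00 and did not pass. The adjusted p was 6.06e-07, and adjusted p = 0.0316 with an estimated correlation.

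Several lists of inflammatory cells passed on the negative side with the preset correlation but not with an estimated one. With fry, which passed 27 of 35 lists, adjusted p was 0.0143 for macrophages, 0.011 for neutrophils and 0.0101 for eosinophils. Among macrophage and monocyte genes, 13 of 21 passed on the negative side, including the complement C1q genes C1qb (-1.99 ± 0.55) and C1qa (-1.64 ± 0.60) and the Fc receptor gamma chain gene Fcer1g (-0.69 ± 0.23). Apoe (0.94) and Gpnmb (0.31) of the same list passed on the positive side (adjusted p = 1.06e-05 for the list, and adjusted p = 0.0986 with an estimated correlation). Of 10 neutrophil genes, 9 passed on the negative side, among them the calprotectin genes S100a8 (-1.13 ± 0.33) and S100a9 (-0.73 ± 0.37) and the chemokine gene Cxcl1 (-1.27 ± 0.56). The list had an adjusted p of 4.79e-05, and adjusted p = 0.0869 with an estimated correlation; the probe of S100a9 lies 24 IDs from that of Mmp12 (-2.30). Of 6 eosinophil genes, 3 passed on the negative side (4 adjusted over the list alone): Rnase2a, the lipoxygenase gene Alox15 (-0.96 ± 0.53) and Ccr3, the eotaxin receptor gene (-0.39 ± 0.33). Siglecf, carried by eosinophils and alveolar macrophages, passed on the positive side at 0.30, and Prg2, the major basic protein gene, gave -0.14 and did not pass. The eosinophil list had an adjusted p of 0.000998, adjusted p = 0.0614 with an estimated correlation and 0.0836 on ranks. Ccr3 lost its call without mouse 2, mouse 3 or mouse 5, with limma adjusted p-values of 0.0884, 0.113 and 0.123 (0.0194 to 0.123 over its 16 alternatives). Its mean ratio was then -0.27, -0.37 and -0.35, against -0.39 over all mice.

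B cell genes were also shifted. Of 12 members 8 passed on the negative side, including the IgM heavy chain gene Ighm (-0.55 ± 0.29), the complement receptor gene Cr2 (-0.28 ± 0.07) and the B cell kinase gene Blk (-0.40 ± 0.26), and Vpreb3 (0.32) passed on the positive side. The call of the list (adjusted p = 0.036) was lost without mouse 1 (adjusted p = 0.165), with quantile normalization (0.0767) and with probes measured on all 5 arrays only (0.0531), and the list gave adjusted p = 0.0614 with an estimated correlation (0.000837 to 0.165 over its 19 alternatives). The estimated correlation of this list was 0, below the preset 0.01. The rise to 0.0614 thus came from the adjustment across lists, not from correlation among its genes. The probe of Cr2 lies 18 IDs from that of the cell cycle gene Cdc45 (-1.01). Blk lost its call without mouse 5 (limma adjusted p = 0.0596; 0.0081 to 0.0596 over its 16 alternatives), and the first of the 2 Ighm probes alone gave -0.91. T cell and natural killer cell genes gave 5 members on the negative side and 1 on the positive side of 23, and mast cell and basophil genes 1 and 1 of 7. Neither of these lists passed, with adjusted p-values of 0.263 and 0.831 in limma's cameraPR. Within them the granzyme gene Gzma had -1.09, the basophil protease gene Mcpt8 -1.20 and the T cell receptor chain gene Cd3e -0.15 (n = 4), which did not pass. Of 17 genes of MHC class II and antigen presentation, 6 passed, all on the negative side, and the list did not (adjusted p = 0.063). It passed under 4 of 19 alternatives, among them leaving out mouse 2 (cameraPR adjusted p = 0.00526), with adjusted p-values up to 0.321.

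Complement and acute-phase genes gave 12 of 21 members on the negative side and 0 on the positive side (12 and 1 adjusted over the list alone), including Saa3, C1qb and the complement factor B gene Cfb (-1.94 ± 0.60). The adjusted p was 4.72e-06, and adjusted p = 0.0614 with an estimated correlation. Interferon response genes gave 15 of 25 on the negative side (18 adjusted over the list alone) and 0 on the positive side, among them Cxcl9, the immunoproteasome gene Psmb9 (-0.57 ± 0.10) and the GTPase gene Irgm1 (-1.18 ± 0.38). The list had an adjusted p of 8.1e-09, and adjusted p = 0.062 with an estimated correlation. Mx1 (-0.04) and Ifit3 (0.06), classical targets of type I interferon, did not pass. Lysosome and cathepsin genes gave 12 of 22 on the negative side (14 adjusted over the list alone), led by prosaposin, Psap (-1.10 ± 0.28), Ctsz (-1.17 ± 0.39) and Ctsa (-0.86 ± 0.34), while Ctsh (0.59) and Cst3 (0.47) were on the positive side. Their adjusted p was 4.65e-05, and adjusted p = 0.118 with an estimated correlation. Endoplasmic reticulum chaperone genes gave 15 of 33 on the negative side and 2 on the positive side (20 and 3 adjusted over the list alone), with Hspa5 (-0.85 ± 0.20), Manf (-0.98 ± 0.26) and Pdia3 (-0.76 ± 0.23). Atf4 (0.23) and Ddit3 (0.35), transcription factors of the stress response, passed on the positive side (adjusted p = 4.79e-05 for the list, and adjusted p = 0.0986 with an estimated correlation). Glycolysis genes gave 6 of 15 on the negative side (8 adjusted over the list alone), with Pgk1 (-0.60 ± 0.23), Pfkp (-0.38 ± 0.11) and Ldha (-0.46 ± 0.20, 17 probes). The list had an adjusted p of 0.00707, and adjusted p = 0.062 with an estimated correlation.

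The 4 lists on the positive side were endothelium, alveolar type 1 cells, heart muscle, and detoxification and antioxidant enzymes. Of 22 endothelial genes, 15 passed there (16 adjusted over the list alone) and 0 on the negative side, with a median of 0.38. Ace, the angiotensin-converting enzyme of lung capillaries, had 0.82 ± 0.27, the endoglin gene Eng 0.64 ± 0.23 and the transcription factor gene Sox18 0.67 ± 0.26, while Pecam1 (0.20) did not pass. The probe of Sox18 lies 6 IDs from a stronger one (1.09). The adjusted p was 1.48e-07, and adjusted p = 0.0986 with an estimated correlation. Of 13 alveolar type 1 cell genes, 9 passed on the positive side (11 adjusted over the list alone), with a median of 0.51. They included the caveolin genes Cav2 (0.65 ± 0.18) and Cav1 (0.46 ± 0.15) and Hopx (0.65 ± 0.19), and the list had an adjusted p of 3.15e-07, and adjusted p = 0.0936 with an estimated correlation. Detoxification and antioxidant genes split, with 14 of 33 on the positive side and 6 on the negative side. Gstm2 (0.78 ± 0.25), Gstt1 (0.52 ± 0.15) and the club cell cytochrome gene Cyp2f2 (0.95) stood against Gclc, the rate-limiting enzyme of glutathione synthesis (-1.04 ± 0.31), haem oxygenase 1, Hmox1 (-0.64), and the metallothionein gene Mt2 (-0.87), whose probe lies 24 IDs from a stronger one. This list had an adjusted p of 0.00851, and adjusted p = 0.0937 with an estimated correlation.

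Heart muscle genes, included as markers of pulmonary vein muscle or carried-over atrium, gave 11 of 21 members on the positive side (13 adjusted over the list alone) and 0 on the negative side. Cox8b, the myosin light chain gene Myl1 (0.52 ± 0.12) and the calcium-binding protein gene Hrc (0.81 ± 0.35) had the smallest p, the atrial myosin light chain gene Myl7 had 0.68, and Myh6 (-0.07), the abundant heart myosin, did not pass. The adjusted p was 1.1e-05, and adjusted p = 0.111 with an estimated correlation. These markers lay on the same side as the endothelial and alveolar type 1 genes.

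The other lists did not pass limma's cameraPR test. Alveolar type 2 genes gave 8 members on the positive and 3 on the negative side of 19: Sftpc (0.67) and Pla2g1b (0.88) against the surfactant protein gene Sftpd (-0.47, n = 4), with an adjusted p of 0.0563. This list passed under 8 of 19 alternatives, among them leaving out mouse 1 (0.0146) or mouse 4 (0.0198), with adjusted p-values from 0.0146 to 0.321. Club cell genes gave 6 and 2 of 17 (7 on the positive side adjusted over the list alone), with an adjusted p of 0.0742. They passed as a list under 2 of 19 alternatives, without mouse 1 (0.00592) and without mouse 4 (0.0408), with adjusted p-values up to 0.52. Arginine and polyamine genes gave 7 on the negative and 2 on the positive side of 18, with the arginine transporter gene Slc7a2 (-1.15) beside Arg1, at an adjusted p of 0.0563. Extracellular matrix genes gave 13 on the negative and 7 on the positive side of 35: the macrophage elastase gene Mmp12 (-2.30) and the fibrillar collagen genes Col1a1 (-0.78) and Col3a1 (-0.75) against Bgn (0.31) and Col4a2 (0.30), with an adjusted p of 0.0716. The matrix list passed under 3 of 19 alternatives, among them leaving out mouse 1 (0.0029), with adjusted p-values from 0.0029 to 0.321. Of 15 genes of type 2 cytokine signalling, 4 passed on the negative side (5 adjusted over the list alone), among them the eosinophil growth factor gene Il5 (-0.84), and 2 on the positive side, including Tslp (0.45), with an adjusted p of 0.263; the probe of Il5 lies 24 IDs from that of Mcm3 (-1.05). Lipid metabolism genes gave 3 on the negative and 4 on the positive side of 20 (adjusted p = 0.0563), immediate early genes 3 and 4 of 21 (0.0656), and smooth muscle genes 3 and 1 of 10 (0.263). Erythrocyte genes gave 3 and 1 of 8 (adjusted p = 0.242), platelet genes 2 and 0 of 4 (0.0742), and ciliated cell genes 2 and 1 of 18 (0.437; 1 and 1 adjusted over the list alone). Housekeeping genes gave 5 and 1 of 14 (adjusted p = 0.062), with Gapdh at -0.42 over 17 probes. Ribosomal protein genes gave 7 and 4 of 53 (adjusted p = 0.201; 6 and 4 adjusted over the list alone). Oxidative phosphorylation genes gave 4 and 9 of 71 (adjusted p = 0.263; 4 and 8 adjusted over the list alone), and proteasome genes 7 and 0 of 30 (adjusted p = 0.17; 5 and 0 adjusted over the list alone).

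**Figure D2:**
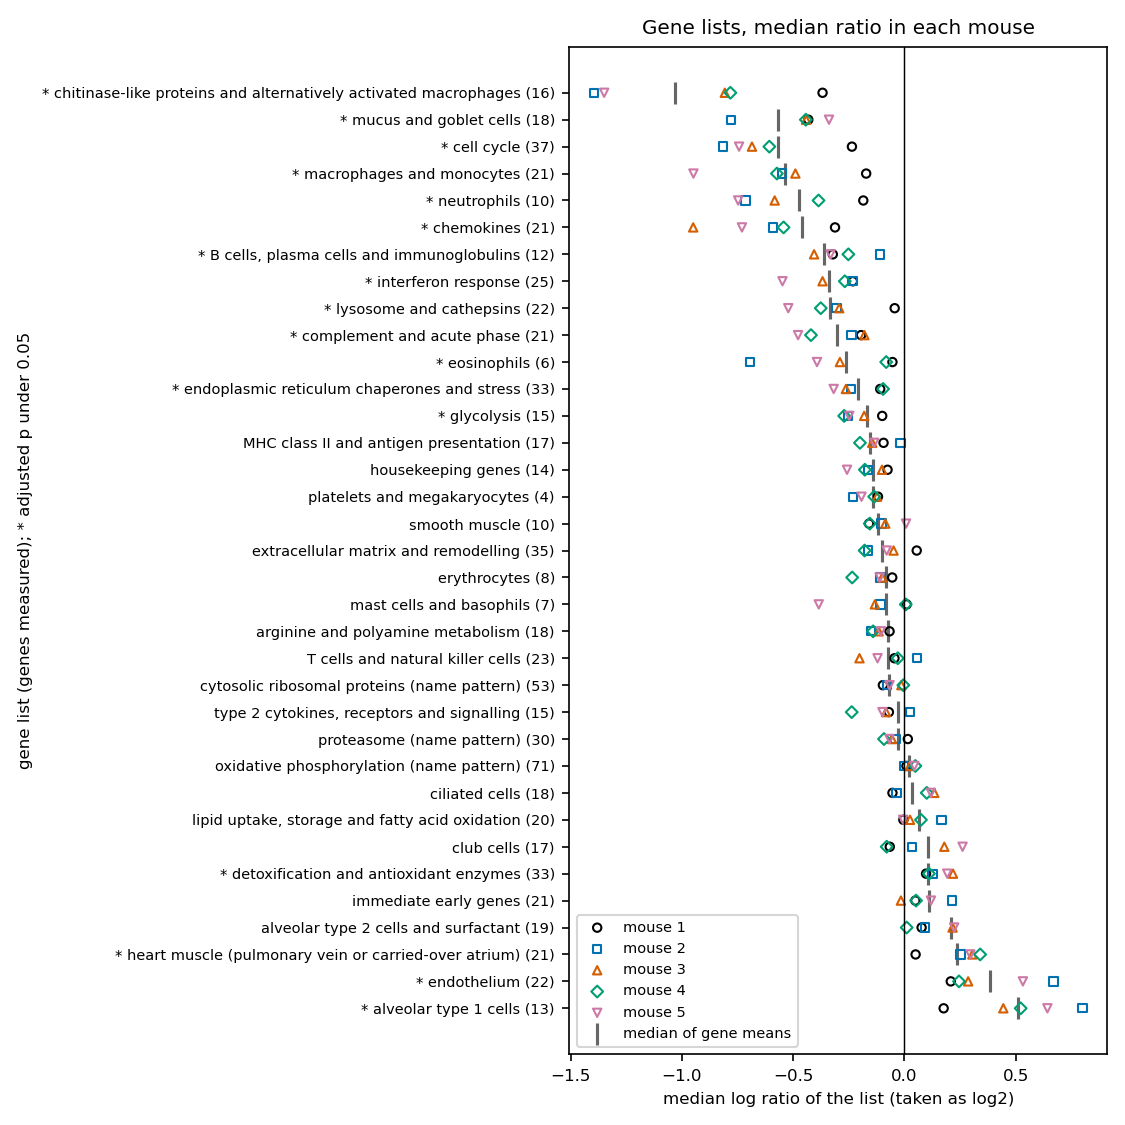
Median log ratio of each of the 35 gene lists (rows, with the number of genes measured) in each ova mouse (symbols) and over gene means (grey bars); the x axis is the deposited log ratio taken as log2, and asterisks mark lists with an adjusted p under 0.05 at the preset correlation. Alternatively activated macrophage genes lie lowest, with a median of -1.03, and alveolar type 1 genes highest, with 0.51.

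Position in the probe order left a trace in the ratios. Mean ratios of probes not naming the same gene correlated at ID distances of 6 (Spearman's rho = 0.187 over 9138 probe pairs), 18 (0.130) and 24 (0.135). Over the other 57 distances up to 60, rho was 0.049 at most. Probes without a gene symbol were kept in these pairs, so some pairs may belong to 1 gene. This is a correlation across probes, which are not independent replicates. Of 153 probes past the threshold and beyond a size of 1, 20 lay at such a distance from a stronger probe not naming the same gene. They included Sar1a, Kctd9, Fgf22 (-2.64, 6 IDs from Arg1) and Fkbp5 (-1.15, 24 IDs from Arg1). Sizes were compared whatever the side, so Gstm1 (1.14) also counted, beside Mrc1 (-1.23) and Mmp12 (-2.30) on the other side. All 678 probes at such a distance from a stronger probe beyond 1 in size, on either side, were then left out. Of these, 239 were past the threshold, against 3095 of all 11714 tested probes. The B cell list lost its call (cameraPR adjusted p = 0.0765), although its median did not shrink: -0.36 over 12 genes before and -0.38 over 10 after. The lists of MHC class II (0.0417), arginine and polyamine (0.0486) and lipid metabolism genes (0.0486) gained calls. Their medians went from -0.157 to -0.169, from -0.0729 to -0.0754 and, for lipid metabolism, from 0.066 down to 0.012. The count of cell cycle genes past the threshold on the negative side moved from 30 of 37 to 25 of 31.

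**Figure D3:**
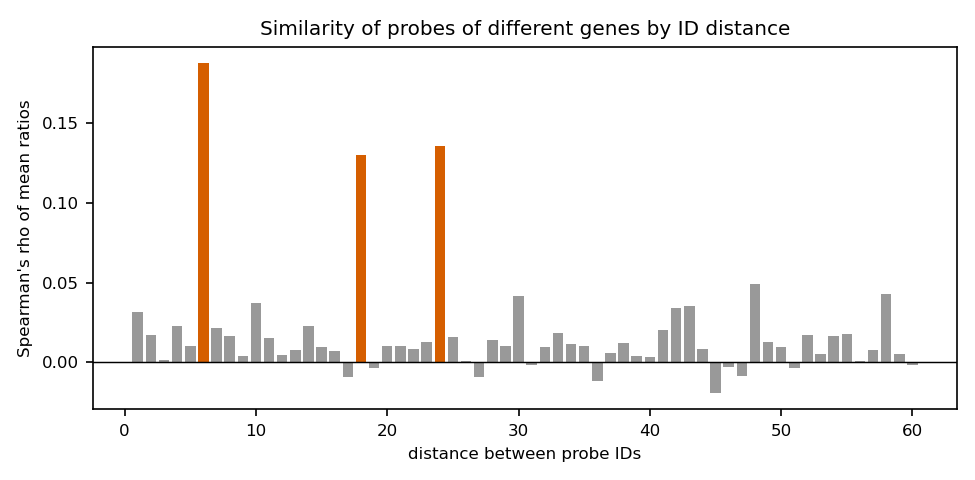
Spearman's rho (y axis) between the mean log ratios of probes not naming the same gene (probes without a symbol kept) against the distance between their probe IDs (x axis, 1 to 60). Distances of 6, 18 and 24 (orange) reach 0.187, 0.130 and 0.135, and the other distances stay at or below 0.049.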

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

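The tests of the side of the response genes, of genes placed side by side and of mouse 1 were chosen after the result was seen, and those on deviations per array and on weak probes before it. Of 108 groups of 4 or 5 values examined, 1 had a sample far from the others. The median of the mucus and goblet cell genes was -0.78 in mouse 2, beyond the other 4 mice, which lay between -0.34 and -0.44. At 1 in 20, 5.4 groups would be expected, but only if they were independent and unselected. They include the named genes, most of them chosen in these data for a large ratio or small p, and lists that share genes. The low count therefore does not show that outliers are rare.

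The first pattern is the side of the response genes. Of 7 genes known to rise in allergic airway inflammation, 0 lay past the threshold above 0, which argues against the reading of the titles, that the deposited ratio is ova over control. In contrast 6 lay past the threshold below 0, and the epithelial markers Sftpc and Scgb1a1 lay above it, consistent with the hypothesis that the deposited ratio is control over ova. Under that hypothesis the inflammatory, mucus and cell cycle genes of the negative side would be more abundant in the ova lungs, and the endothelial and alveolar type 1 genes less abundant. The labels and the deposited table do not settle it, and the test takes the textbook direction of these genes for granted.

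The second pattern is the similarity of probes 6, 18 and 24 IDs apart. Genes of related function placed side by side in the probe order are argued against, because rho was 0.031 at most over distances 1 to 5. A candidate explanation is material carried from a neighbouring spot or well: the deviations of single arrays from each probe's mean also correlated, with a mean rho of 0.175 at distance 6, 0.130 at 18 and 0.161 at 24, against 0.068 at most over the other 57 distances. A local gradient on the slide stays open, since weak probes correlated about as much (rho = 0.160), it would also give correlated deviations, and the slide layout is not used here. Of probes at distance 6 from a probe beyond 1 in size, 13.4% had a mean ratio beyond 0.5 on the same side as that probe. The share was 9.41% at 18 and 12.6% at 24. Over the other distances its median was 4.74% and its highest value 9.01%, so that 18 stands little above the highest of them.

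The third pattern is the size of the ratios in mouse 1, 0.453 of the mean of the other 4 mice (quartiles 0.285 and 0.621). It was less marked in the largest ratios. Over the 22 genes whose mean in the other mice was beyond 2 in size, the median quotient was 0.662 (quartiles 0.475 and 0.776). This was 1.47 times the median of 0.449 over 713 genes, against 0.84 to 1.07 times for the other mice. A single factor on every ratio was tested by the genes that left 0.449 times the mean of the other mice (limma, Benjamini-Hochberg adjusted). In mouse 1, 4 of 713 did: Retnla (quotient 0.903, adjusted p = 0.00435), Clca1 (0.821, 0.00663), Kctd9 (0.998, 0.00992) and Nadsyn1 (1.10, 0.0359). These 4 argue weakly against a single factor on every ratio. Each other mouse gave 0 genes, but its reference spread included the small ratios of mouse 1, which can widen it and weaken the test. For Clca1 the SD was 0.208 without mouse 1 and 0.403 over all 5 mice. The contrast of 4 with 0 is thus partly built in and is no evidence of its own. Probes of Kctd9 and Nadsyn1 lie beside stronger ones, and with each gene's own SD in place of limma's the share beyond a 99% limit, 0.561%, was within the range of the other mice (0.181% to 0.568%). A factor on most ratios stays open, since with limma's spread 1.54% of the genes lay beyond that limit, against 0.726% to 2.08% in the other mice. It and a smaller response in the lungs of mouse 1 cannot be told apart, because the files hold neither a measure of inflammation nor the spot brightness.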

How the results depend on the processing

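Leaving out neighbouring probes, subtracting window medians and the sign assignments were chosen after seeing the data. The count of probes past the threshold, 3095, was 2940, 2173, 1869, 2487 and 1862 without mice 1 to 5, so it ranged from 1862 to 2940, with 1065 (without mouse 3) to 1662 on the negative side and 773 (without mouse 5) to 1278 on the positive side. Only the test against a minimum size of 0.5 moved it further, to 72 probes (67 negative, 5 positive), by its construction. The other probe-level alternatives gave between 2860 and 3396 probes, of which between 54.7% and 56.2% were negative. For the lists, 17 calls became 4 with an estimated correlation and 27 with fry, which asks a different question; the other alternatives gave between 16 and 21. Of 665 list values under 19 alternatives, 18 lost and 42 gained a call and 0 reversed; the gains were most frequent for alveolar type 2 cells (8 alternatives), lipid metabolism (6) and housekeeping genes (5). Most of the 69 named genes were chosen for a large ratio or small p in these data, and 68 were past the threshold. Their stability is therefore partly built in and does not stand for all genes. Of 1092 values of the 69 named genes, 1085 kept their call and direction and 4 lost the call (Ccr3 without mice 2, 3 and 5, and Blk without mouse 5). The other 3 were of Il13ra2, which never passed and turned to the negative side with arrays scaled to equal spread (-0.0097), quantile normalization (-0.011) and without mouse 3 (its range without each mouse in turn was -0.0377 to 0.054); the cause was not tested. The median r between arrays stayed between 0.717 and 0.764. No paired analysis was possible because the series holds 1 group against a common pool. Of the 16 sign assignments of the 5 arrays, only 1, the real one, gave 3095 probes, and the highest of the others gave 0. With 16 assignments a share under 0.05 cannot be reached. The shared pool also pushes all arrays the same way, so this count cannot separate an effect of ovalbumin from deviations of the pool. Signal over background is unknown, so a ratio near 0 may be a faint spot. The simulation held no spot brightness and cannot address this. It found 44.6% of shifts of 0.3 with 200 of 11714 probes shifted, a share that need not hold where more probes differ.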

Other observations

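Some gene families had members on opposite sides; all genes here were set together after their values were seen, and the groups have no test of their own. Among latent TGF-beta binding protein genes, Ltbp1 had -1.59 ± 0.22 (n = 5, limma adjusted p = 7.64e-05), while Ltbp3 (0.62 ± 0.33) and Ltbp4 (1.07 ± 0.46) lay above 0 in every mouse. Of genes induced by glucocorticoids, Tsc22d3 (0.63), Dusp1 (0.72), Per1 (0.34) and Klf15 (0.76) were past the threshold on the positive side, and Mt2 (-0.87) and Fkbp5 (-1.15) on the negative side, both with probes 24 IDs from a stronger one, while Sgk1 (0.18) and Zbtb16 (0.14, n = 4) did not pass. Heat shock and co-chaperone genes lay on both sides: beside Hspa8 and Hspa1a, Cryab (0.60), Fkbp4 (0.28) and Bag3 (0.21) passed on the positive side. Hsp90aa1 (-0.55, its probe 6 IDs from that of Tff2), Hspa4l (-0.54), Stip1 (-0.29) and Hspd1 (-0.24) passed on the negative side, and Hsph1 (-0.11), Hspe1 (-0.12), Hspa4 (-0.12) and Dnaja1 (0.16, n = 4) did not pass.

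Several genes known from fat tissue passed on the positive side: Adipoq, carbonic anhydrase 3, Car3 (0.93 ± 0.46 over 2 probes, of which 1 alone passed, at 1.44), the brown fat genes Cidea (0.64 ± 0.15) and Ucp1 (0.42 ± 0.20), and Cidec (0.24) and Lep (0.19, n = 4). The lipase gene Lipe gave -0.03 and did not pass. Adipoq and Car3 were lowest in mouse 3, at 0.17 and 0.35, and Cidea and Ucp1 in mouse 4, at 0.44 and 0.08. Of 10 genes with 17 probes each, Top1 had the smallest SD between probes, 0.039 around a mean of 0.22, and Hspa1a the largest, 0.381, from 0.057 to 1.49. Of 568 genes with several tested probes, 235 had at least 1 past the threshold, 17 had all probes past it on 1 side, and 10 had probes past it on opposite sides.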
